A study of Mus musculus with 6 samples.

How the data were processed

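RNA was measured in glomeruli from 6 mice, 3 wild type (WT) and 3 homozygous for the MCTO allele of Mafb, with 1 library per mouse. Per the labels' protocols, libraries were made from 250 ng of total RNA after depletion of ribosomal RNA, with a kit that keeps strand information, and read as 36-base pairs on a NextSeq500. The deposited values are raw counts of reads per gene name, with no normalization. Per the file headers, reads were counted with featureCounts 2.0.1 over exons of the Ensembl release 102 annotation of GRCm38, summed by gene name. The counting command used no strand option, so a read on either strand counted for a gene. It also counted each mate of a pair as a read, and left out reads that mapped to several places or fell in several genes. Reads in exon parts shared by genes on opposite strands are thus missing from both. Short reads from near-identical genes, such as Hspa1a and Hspa1b, are therefore under-counted. The aligner is not given in the sources used here. Per the submitters' processing notes, Subread 2.0.1 and edgeR 3.36.0 were used.

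Groups were taken from the sample titles and genotype labels. One protocol text in the labels calls the MCTO mice controls, whereas the titles and genotype labels set them against wild type. WT was taken as the reference, and the direction of every fold change rests on this choice. The file held 55367 gene names, and every column of values was assigned to 1 of the 6 libraries. Total counts ranged from 7446612 to 13713436 reads per library. Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 18734 genes holding at least 99.6% of the reads of each library. Size factors were computed by TMM. MCTO was tested against WT with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust estimation of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all genes kept. A gene was called at an adjusted p under 0.05. Fold changes are MCTO over WT on the log2 scale. Their standard errors (SE) are the size of the log2 fold change divided by the square root of its F statistic. They were not estimated apart from the test, also for genes with few reads in 1 group. Levels are CPM, read counts relative to library size scaled by TMM, as mean ± SD of 3 libraries. Where 1 group had no reads, the fold is a lower bound set by 3 reads over that group. Where a group had 1 to 3 reads in all, the ratio is given with its 95% interval from counting alone. Such intervals and bounds cover counting error only, since amplified reads and the mates of a pair are not independent molecules.

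Gene lists for cell types and pathways, 30 in all, were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, except where stated. The lists hold 832 genes, of which 27 are in more than 1 list. Lists with at least 5 measured members, 28 in number, were tested with limma 3.58.1 (camera) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list was also tested with an estimated correlation and with fry, which asks whether members move one way on balance and does not compare them with other genes. List p-values were adjusted over the 28 lists. Calls of members are given over all genes tested and adjusted over the list alone.

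The genes named are Mafb, then the 10 rising and 10 falling genes with the largest fold change among called genes with a mean CPM of at least 2 and no overlap between the groups. Predicted-gene names, clone names and structural RNA genes were left out. Up to 4 members of each list, those with the smallest p, were added. Other called members of a list are named as the content of its count. Positions are those in the deposited table, on GRCm38.

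The alternatives were DESeq2 size factors, upper-quartile size factors or library totals in place of TMM, no filter or a stricter filter on low counts, DESeq2 1.42.0 and limma-voom in place of edgeR, the replicate number as a block, each library left out in turn, structural and mitochondrial RNA left out of the counts, and the mean of the proximal tubule or structural RNA list as a covariate. A minimum of 2-fold change and an adjusted p under 0.01 were also tried. For the list tests, the tubule covariate and upper-quartile factors were added after seeing the data.

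The test was run on 10 simulated data sets of the MCTO and WT comparison, with 200 changed genes in each and 18292 to 18417 genes tested. It recovered a mean of 14.6% of genes changed 1.5-fold, 58.8% of those changed 2-fold and 97% of those changed 4-fold. The changed genes were drawn only from genes above a minimum mean count, so recovery at lower counts is not covered. A mean of 11.6% of its calls were false, above the nominal 5% level, with 5 to 24 false calls per set. With no gene changed, 7 genes were called. A simulated list of 30 genes raised by 0.4 on the log2 scale gave a camera p of 7.88e-14, and 1 of 100 unchanged lists had a p under 0.05. Each gene was simulated on its own, so members of a list did not move together. In the real lists the estimated correlation ranged from −0.114 (erythrocyte) to 0.872 (proximal tubule). The simulation therefore does not show how camera performs on lists of correlated genes. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.83 to 24.9, so none was taken as a repeat of another.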

Results

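Glomeruli, the filtering units of the kidney, were compared by RNA sequencing between 3 wild-type (WT) mice and 3 mice homozygous for the MCTO allele of Mafb. MCTO stands for multicentric carpotarsal osteolysis, a disorder of bone that can be accompanied by kidney disease. Mafb encodes a transcription factor of podocytes, the epithelial cells that cover glomerular capillaries, and of macrophages. All mice were C57BL/6J and 10 weeks old. The WT libraries held 13713436, 11059688 and 7446612 counted reads, and the MCTO libraries held 10960483, 12867158 and 9966011. The comparison asked which genes differ between MCTO and WT glomeruli, and the title of the study names PI3K/AKT signalling as a pathway of interest.

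Mafb itself, at 160363703 to 160367065 on the minus strand of chromosome 2 (GRCm38), was measured at 385 ± 15.5 CPM in WT and 308 ± 46.1 CPM in MCTO glomeruli (SD, n = 3 each). The 3 WT libraries lay at 377, 375 and 403 CPM and the 3 MCTO libraries at 260, 311 and 352 CPM. The log2 fold change was −0.32 ± 0.12 (SE), which did not pass the threshold (adjusted p = 0.266 by edgeR). The labels name an allele and no deletion, so the level of Mafb does not check the genotype.

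Large changes went in both directions, with Padi4 almost absent from WT and Wif1 almost absent from MCTO glomeruli. Padi4, which encodes an enzyme that converts arginine in proteins to citrulline, rose from 0.215 ± 0.104 to 36.2 ± 4.64 CPM. Pamr1, a gene for a secreted protease-like protein, rose from 5.45 ± 0.667 to 94.9 ± 6.39 CPM, and R3hdml rose from 3.48 ± 0.850 to 116 ± 15.9 CPM. Wif1, a secreted inhibitor of Wnt signalling, fell from 22.3 ± 3.26 to 0.0267 ± 0.0462 CPM, and Ntrk3, the receptor for neurotrophin-3, fell from 182 ± 13.5 to 19.95 ± 2.61 CPM. The values are means ± SD of 3 libraries.

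In all, 319 genes were higher and 207 lower in MCTO among 18734 genes tested (edgeR, adjusted p under 0.05), and 157 of the former and 89 of the latter changed at least 2-fold. The 3 MCTO libraries did not overlap the 3 WT libraries at any of the 526 called genes. The call itself favours such genes, so this is no separate support. Over all genes tested, the groups did not overlap for 16.9%, where chance gives 10%. An unadjusted p under 0.05 was found for 2040 genes, where 937 were expected by chance. Of 524 called genes matched to an annotated symbol, 471 were protein coding. The first principal component held 34.1% of the variance and separated the genotypes. The second held 24.6% and separated WT 1, WT 2 and MCTO 2 from the others, the 3 libraries with the highest means of the proximal tubule list. With libraries scaled by their totals alone, 376 genes were higher and 131 lower, so that 74.2% of calls were higher against 60.6% with TMM, and the median of all genes moved from 0.004 to 0.101. Without WT 2, 166 genes were higher and 115 lower, and without WT 3, 134 were lower.

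Among the 10 higher genes, Qrfprl, related to receptors for RFamide peptides, had no read in the WT libraries and 270 in the MCTO libraries, at least 81.3-fold higher over the group. Mmp10, a matrix metalloproteinase, had 3 reads in WT and 278 in MCTO, a ratio of 81.9 (95% counting interval 27.7 to 399). Its call (adjusted p = 0.0232 by edgeR) was lost without WT 1 (0.109), WT 2 (0.123), WT 3 (0.0607) or MCTO 3 (0.0823), and with limma-voom (0.111). Padi4, at 140745865 to 140774236 on chromosome 4, rose by 7.25 ± 0.28 on the log2 scale (SE, adjusted p = 1.91e-08 by edgeR). The log2 fold changes of the others were 5.95 ± 0.56 for Stac2, 5.08 ± 0.18 for R3hdml, 4.83 ± 0.58 for Npas3, a transcription factor gene, and 4.81 ± 0.41 for Hpgds, a prostaglandin D synthase. Gdpd2 rose by 4.43 ± 0.24, Insyn1 by 4.23 ± 0.34 and Pamr1 by 4.11 ± 0.14. Hpgds, at 65117293 to 65144908 on chromosome 6, and Qrfprl, at 65381105 to 65458150, lie close together.

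Among the 10 lower genes, Wif1, at 121033960 to 121100650 on chromosome 10, had 680 reads in WT and 1 in MCTO, a ratio of 770 (95% counting interval 138 to 30400). Lingo2 had 374 reads in WT and 3 in MCTO, a ratio of 141 (47.9 to 687). The log2 fold change was −4.70 ± 0.30 (SE) for Kcng2, a potassium channel subunit gene, and −3.86 ± 0.49 for Sla, a gene for an adaptor of receptor signalling. It was −3.52 ± 0.28 for Ube2ql1, −3.47 ± 0.33 for Creg2, −3.24 ± 0.33 for Opcml and −3.23 ± 0.23 for Fgfbp1, whose product binds fibroblast growth factors. Ntrk3 was at −3.19 ± 0.13 (adjusted p = 2.48e-08 by edgeR) and Gbx1, a homeobox gene, at −3.04 ± 0.34. Exons of Kcng2 overlap those of the antisense gene D330025C20Rik (log2 fold change −3.17), and reads within the shared parts were not counted.

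**Figure D1:**
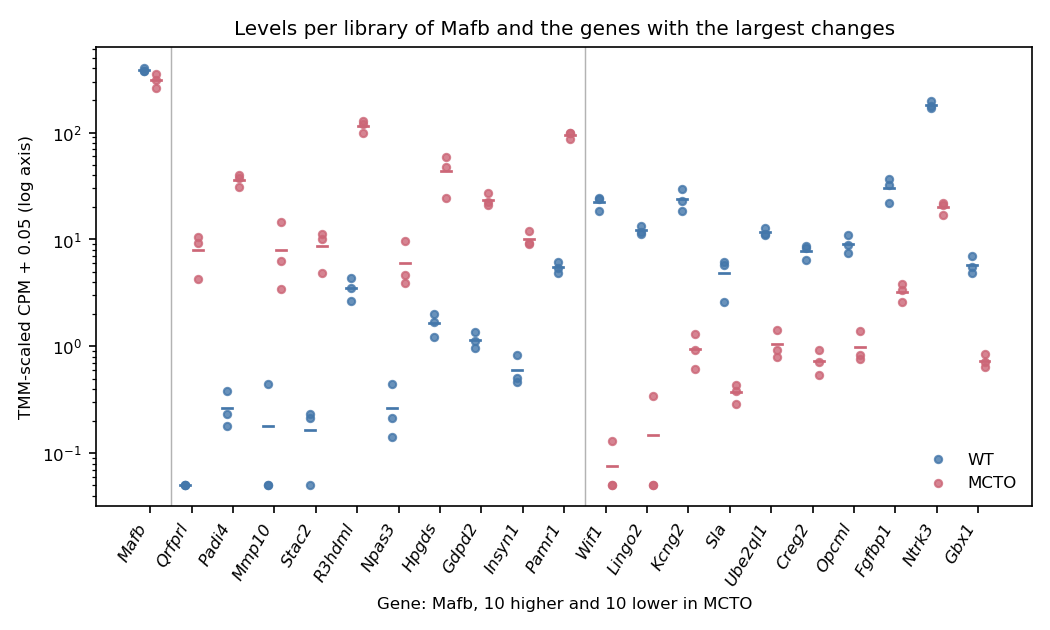
TMM-scaled CPM plus 0.05 on a log axis for Mafb and the 10 higher and 10 lower genes named by rule. Each point is 1 library (blue WT, red MCTO) and each line the mean of 3. The groups do not overlap at any of the genes, which the naming rule required of all but Mafb. Mafb lies at 260 to 352 CPM in MCTO against 375 to 403 CPM in WT.

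Podocyte genes moved in both directions. Of 47 measured, 12 rose and 4 fell over all genes tested, and 23 rose and 5 fell when adjusted over the list alone. Higher genes included Nphs1 and Nphs2, which encode nephrin and podocin of the slit diaphragm (0.72 ± 0.12 and 0.57 ± 0.12), Tcf21, a transcription factor gene (1.20 ± 0.15), and Enpep, aminopeptidase A (0.93 ± 0.11). Npnt, Robo2, Iqgap2, Clic5, Gas1, Kirrel, Srgap1 and Myo1e also rose. Tdrd5 fell from 330 ± 34.6 to 80.4 ± 16.7 CPM (log2 fold change −2.04 ± 0.15, SE) and Sema3g, a secreted semaphorin, from 1358 ± 185 to 444 ± 49.2 CPM (−1.61 ± 0.13). Pard3b (−0.62 ± 0.11) and Pla2r1 (−0.58 ± 0.14) fell as well. The list as a whole was higher by limma's camera test (adjusted p = 0.000589; adjusted p = 0.607 with an estimated correlation). The number of members that rose was 5 without WT 2, 5 without WT 3, 6 without MCTO 3, and 8 without WT 1, and 19 with no filter on low counts.

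Some genes of the glomerular basement membrane and of fibrillar matrix rose. In the basement membrane list, Col18a1, the collagen XVIII chain, rose from 531 ± 48.8 to 1050 ± 51.6 CPM (log2 fold change 0.98 ± 0.11, SE), and Crim1 (0.57 ± 0.10) and Nid2 (0.57 ± 0.12) rose too. They were 3 of 20 measured, with none lower, and 6 rose when adjusted over the list alone. The number that rose was 1 with the mean of the structural RNA list as a covariate and 5 with no filter on low counts. Lamb2 (0.40 ± 0.11) did not pass over all genes. In the fibrillar and interstitial matrix list, 7 of 34 measured rose and 1 fell, or 11 and 3 adjusted over the list alone, and 12 had a negative fold change. The number that rose was 4 without WT 2 and 4 with the structural RNA covariate, and 2 fell without WT 1, with no filter or with the proximal tubule mean as a covariate. The list median of 0.26 was 0.15 without WT 1 and 0.09 without MCTO 3. Both chains of collagen I rose, Col1a2 from 184 ± 16.9 to 568 ± 89.5 CPM (1.63 ± 0.13) and Col1a1 by 1.38 ± 0.25. The collagen crosslinking enzymes Loxl1 (1.53 ± 0.21), Loxl2 (0.998 ± 0.13) and Lox (0.99 ± 0.23) rose with Sparc and Tnc, whereas Col15a1 fell (−1.32 ± 0.13). By camera both lists were higher, with adjusted p = 0.00569 for the basement membrane and 0.00401 for fibrillar matrix. Each had an adjusted p = 0.594 with an estimated correlation. Both calls were lost without WT 1 (adjusted p = 0.0891 for each), and that of fibrillar matrix also without MCTO 3 (0.0623) and on ranks (0.0526). Exons of Crim1 and Nid2 overlap those of Fez2 and Rtraf on the other strand.

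The endothelial and mesangial genes called were all lower. Of 32 glomerular endothelial genes, 11 fell and none rose, or 20 adjusted over the list alone. Kdr and Flt1, both receptors for vascular endothelial growth factor, fell (log2 fold change −0.94 ± 0.13 and −0.67 ± 0.11, SE), and Emcn, endomucin, fell from 122 ± 14.0 to 67.9 ± 4.71 CPM. Ehd3 (−0.62 ± 0.12), Plvap, Pi16, Cldn5, Tie1, Ptprb, Cyyr1 and Cdh5 also fell. Of 19 mesangial genes, which mark the contractile cells between the capillaries, 8 fell and none rose, or 12 adjusted over the list alone. They were Gucy1a1 and Gucy1b1, the subunits of soluble guanylate cyclase (−0.86 ± 0.13 and −0.66 ± 0.15), Ptn (−0.85 ± 0.12), Agtr1a, the angiotensin II receptor (−0.58 ± 0.11), Art3 (−0.82 ± 0.16), Des, Sfrp2 and Itga8. By camera the adjusted p was 3.36e-11 for the endothelial list and 3.59e-08 for the mesangial list, and adjusted p = 0.384 and adjusted p = 0.57 with an estimated correlation. By fry the endothelial list passed (adjusted p = 0.0212) and the mesangial list did not (0.0558). With library totals alone, 5 endothelial and 3 mesangial members fell, and 17 endothelial members fell with no filter on low counts. The number of endothelial members that fell was 4 without WT 1, WT 3 or MCTO 3 and 7 without WT 2 or MCTO 2. That of mesangial members was 3 without WT 3 or MCTO 3 and 4 without WT 2 or MCTO 2.

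**Figure D2:**
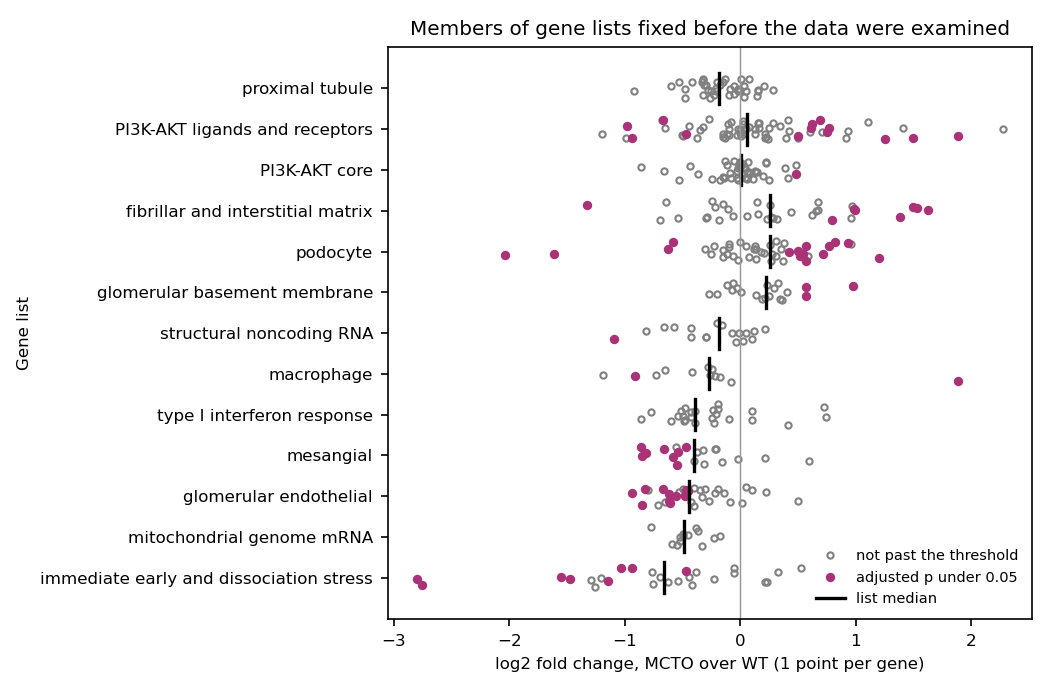
Log2 fold change, MCTO over WT, of each measured member of 13 gene lists, the 10 called by camera, both PI3K-AKT lists and the proximal tubule list. Filled points passed an adjusted p of 0.05 over all genes, open points did not, and black bars are list medians, −0.44 for the endothelial and 0.26 for the podocyte list.

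The heat shock and immediate early genes called were all lower in MCTO glomeruli. Of 26 measured, 8 fell and none rose, or 11 adjusted over the list alone. Hspa1b and Hspa1a, near-identical genes for the inducible chaperone HSP70, fell (log2 fold change −2.76 ± 0.36 and −2.80 ± 0.40, SE), as did Hspb1 (−1.55 ± 0.25) and Dnajb1 (−0.94 ± 0.18). Hsph1, Zfp36 (−1.03 ± 0.20), Jun and Atf3 fell too. The mean log2 CPM of the list was 5.32, 6.07 and 5.94 in the WT libraries and 5.08 to 5.09 in the MCTO libraries. The camera test gave adjusted p = 4.74e-08, and adjusted p = 0.594 with an estimated correlation. The number of members that fell was 13 without WT 1, 3 without WT 2, 5 without WT 3, 1 without MCTO 1 and 3 without MCTO 3.

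Csf1r, the receptor for colony stimulating factor 1 and a macrophage marker, rose from 17.1 ± 2.84 to 63.3 ± 7.91 CPM (log2 fold change 1.89 ± 0.15, SE, adjusted p = 1.17e-05 by edgeR). The mannose receptor gene Mrc1 fell from 78.0 ± 4.62 to 41.5 ± 2.78 CPM. They were the only called genes of 12 measured in the macrophage list, and 1 rose and 3 fell when adjusted over the list alone. H2-Aa (−1.19 ± 0.37) and Cd74 (−0.66 ± 0.20) did not pass over all genes. The list was lower by camera (adjusted p = 0.0449; adjusted p = 0.594 with an estimated correlation), a call lost without WT 1 (0.15), WT 3 (0.533), MCTO 1 (0.0576), MCTO 2 (0.0858) or MCTO 3 (0.0602). It was also lost with the replicate block (0.0511), with no filter on low counts (0.134) and without structural and mitochondrial RNA (0.0573). Exons of Csf1r overlap those of Hmgxb3 on the other strand (log2 fold change 0.31, not called). Of lymphocyte genes 2 were measured, Ighm and Cd8a, and of neutrophil genes none, so these lists were not tested.

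For PI3K/AKT signalling, few genes of the pathway core were called, while ligands and receptors moved in both directions. These are mRNA levels, which do not measure the activity of the pathway. Over all genes tested, 526 of 18734 were called. Of 44 measured core genes, 1 rose, Pik3r1, a regulatory subunit of PI3K, from 197 ± 0.650 to 274 ± 22.2 CPM (log2 fold change 0.48 ± 0.10, SE). Adjusted over the list alone, 3 rose. With no filter on low counts, and with the proximal tubule covariate, 3 rose and 1 fell, and with the structural RNA covariate 0 were called by edgeR. The call of Pik3r1 (adjusted p = 0.0198 by edgeR) was lost without WT 1 (0.0811), WT 2 (0.118), WT 3 (0.0855), MCTO 1 (0.0549) or MCTO 3 (0.0905). Pik3cb (0.48 ± 0.13), Rictor (0.42 ± 0.11) and Pik3cd (−0.86 ± 0.25) did not pass over all genes. The core list had a median of 0.01, a mean of −0.01 and an upward camera direction (adjusted p = 0.823), which was downward without WT 1 (0.773) or MCTO 3 (0.965) and with the proximal tubule covariate (0.953). Of 66 measured ligand and receptor genes, 9 rose and 4 fell, or 16 and 9 adjusted over the list alone. The number that rose was 4 without WT 2, 5 without WT 1 or MCTO 1 and 3 with the structural RNA covariate, and 8 fell with no filter on low counts. Higher were Csf1r, the integrin subunits Itga2 (1.25 ± 0.15), Itga3 (0.69 ± 0.10) and Itgav, and Epha2, Fgfr2, Kitl, Tnc and Spp1. Lower were Kdr, Flt1, Pdgfra and Itga8. The camera test of this list did not pass (adjusted p = 0.157).

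Of 15 parietal epithelial genes, which mark the cells lining Bowman's capsule, 2 rose, Cldn1 (2.00 ± 0.18) from 6.43 ± 0.957 to 25.9 ± 3.08 CPM and Aldh1a2 (1.94 ± 0.21) from 3.47 ± 0.442 to 13.5 ± 1.31 CPM. The count was also 2 adjusted over the list alone, and the median of the list was −0.05, its mean 0.34 and its camera direction upward (adjusted p = 0.11; adjusted p = 0.686 with an estimated correlation). The list passed as higher without WT 2 (0.00783), WT 3 (0.0121) or MCTO 2 (0.00184, median 0.22), and with no filter on low counts (0.0195). In the inflammatory list, the chemokine gene Cxcl12 (0.85 ± 0.12) and Il18 (1.80 ± 0.34) rose of 14 measured, or 2 adjusted over the list alone (camera adjusted p = 0.449, upward, with a median of −0.02 and a mean of 0.12). In the complement list, C1ra (1.28 ± 0.22) and Cd55 (0.70 ± 0.15) rose and Cfh (−0.95 ± 0.22) fell of 15 measured, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.449). In the smooth muscle and renin cell list, Acta2 (0.55 ± 0.13) rose and Mylk (−0.65 ± 0.12) fell of 14 measured, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.631). In the tubular injury list, Tnfrsf12a (0.95 ± 0.17) and Spp1, osteopontin (0.77 ± 0.17), rose of 23 measured, or 2 adjusted over the list alone (camera adjusted p = 0.644), and 1 member fell without MCTO 1, where the list pointed downward (0.429). None rose by edgeR without WT 2, and with the structural RNA covariate 0 rose and 1 fell, with a median of −0.20 against 0.09. The number that rose was 1 with DESeq2 size factors, the stricter filter or limma-voom, without structural and mitochondrial RNA, and without WT 1, WT 3, MCTO 1 or MCTO 2. E2f1 (−1.19 ± 0.18) fell of 24 measured cell cycle genes, or 1 adjusted over the list alone (camera adjusted p = 0.724). The globin gene Hbb-bs (−1.74 ± 0.40) fell of 5 measured erythrocyte genes, or 1 adjusted over the list alone (camera adjusted p = 0.663, downward, with a median of 0.01 and a mean of −0.54). The calls of Acta2, Spp1, Cfh and Hbb-bs were each lost on leaving out any of at least 4 single libraries, and that of Cd55 without WT 2 (adjusted p = 0.142 by edgeR), WT 3 (0.0741), MCTO 1 (0.0982) or MCTO 3 (0.124). With the structural RNA covariate, 0 complement, smooth muscle and renin cell, erythrocyte and cell cycle members were called by edgeR, and 1 inflammatory member rose. Tnfrsf12a lost its call without WT 2 (0.0559) and Mylk without WT 1 (0.0576).

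RNA of the mitochondrial genome and structural RNA moved with genotype in part. Mitochondrial ribosomal RNA took 28.8, 22.1 and 20.4% of counts in the WT libraries and 15.4, 20.7 and 17.1% in the MCTO libraries. None of 13 mitochondrial mRNAs was called by edgeR, though 7 had an unadjusted p under 0.05, and 5 fell when adjusted over the list alone. DESeq2 called 2 lower, mt-Nd3 (adjusted p = 0.0397) and mt-Atp6 (0.0434), and limma-voom called mt-Atp6 (0.0443). By edgeR 8 were lower without MCTO 2, 5 with no filter on low counts, 3 with the proximal tubule covariate and 1 with upper-quartile factors. The median was −0.49 and the camera test passed (adjusted p = 3.2e-06; adjusted p = 0.594 with an estimated correlation). In the structural noncoding RNA list, Scarna13 (−1.09 ± 0.22) fell of 18 measured, or 1 adjusted over the list alone, and 0 fell by edgeR without WT 1, WT 3 or MCTO 1. The list was lower by camera (adjusted p = 0.0276; adjusted p = 0.594 with an estimated correlation). That call was lost without WT 1 (0.094), WT 3 (0.0702) or MCTO 1 (0.374). With the mean of the structural RNA list as a covariate, 197 genes were higher and 94 lower, 255 of them among the 526 called without it. Under this covariate 8 podocyte members were higher and 2 lower, and 3 endothelial, 2 mesangial and 0 heat shock and immediate early members were lower by edgeR. The list medians were 0.28, −0.46, −0.39 and −0.75, against 0.26, −0.44, −0.40 and −0.66 without it. Other medians moved more with the covariate. That of mitochondrial mRNA went from −0.49 to −0.11, of the proximal tubule list from −0.18 to 0.31, of the macrophage list from −0.27 to −0.55 and of the interferon list from −0.39 to −0.53. Over the 8 heat shock and immediate early members called without it, the median size of the log2 fold change went from 1.31 to 1.15 and the median SE from 0.23 to 0.32. Over all 526 genes these medians went from 0.96 to 0.97 and from 0.15 to 0.19. Over the called endothelial members they went from 0.61 to 0.51 and from 0.12 to 0.16. The median size of the fold change rose from 0.62 to 0.72 over the called mesangial and from 0.6 to 0.67 over the called podocyte members. The covariate correlated with genotype (r = −0.678), which widens the SE, and in the heat shock and immediate early list the SE grew by a larger share than the fold changes shrank.

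Tubular genes differed between libraries more than between genotypes. Of 39 proximal tubule genes none was called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05 by edgeR, and their mean log2 CPM was 7.43, 7.25 and 6.22 in the WT and 6.43, 7.46 and 6.59 in the MCTO libraries. With this mean as a covariate, 436 genes were higher and 364 lower, and they held all 526 genes called without it. None of 28 loop, distal tubule and collecting duct genes was called by these 3 tools, and 2 had an unadjusted p under 0.05 by edgeR. Camera did not pass for either list with all 6 libraries (adjusted p = 0.209 and 0.157). The proximal tubule list passed as lower without WT 3 (4.93e-07) or MCTO 2 (2.05e-05) and pointed upward without WT 1 (0.663) or MCTO 1 (0.772), with medians of −0.57 to 0.09 over the libraries left out. With an estimated correlation it gave 0.873. The loop and distal list passed as higher without MCTO 3 (0.0389) and pointed downward without MCTO 1 (0.923). By edgeR, 1 proximal tubule member fell with no filter or the replicate block, and 1 rose and 1 fell with the tubule covariate. Of loop and distal members, 1 rose with no filter and 2 with the tubule covariate. With the structural RNA covariate the medians went from −0.18 to 0.31 and from 0.14 to −0.05.

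**Figure D3:**
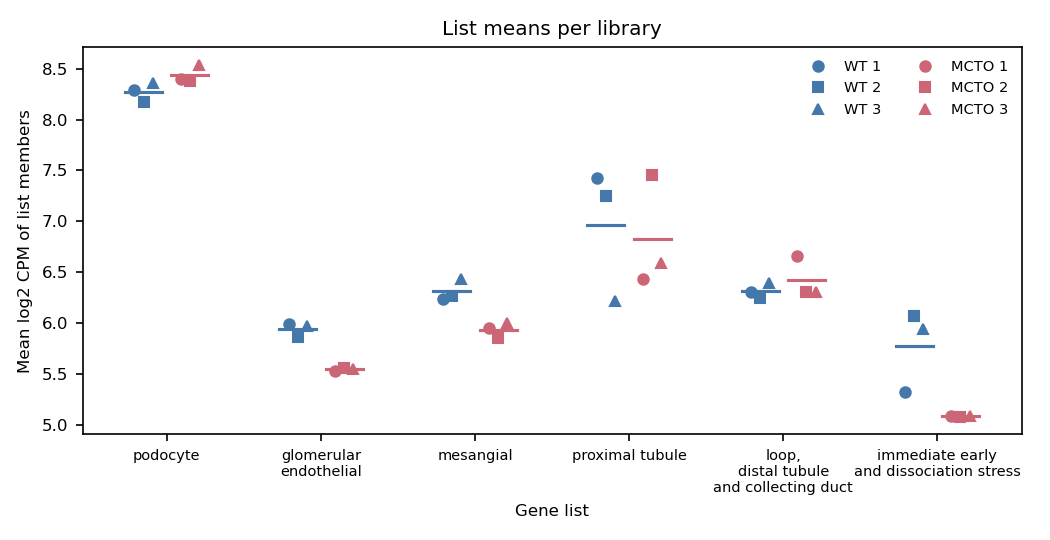
Mean log2 CPM of the members of 6 gene lists in each library (blue WT, red MCTO, symbols for replicates 1 to 3, lines for group means). The endothelial and mesangial means are lower in each MCTO library than in each WT library, whereas the proximal tubule means span 6.22 to 7.43 in WT and 6.43 to 7.46 in MCTO.

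No member passed over all genes by edgeR, DESeq2 or limma-voom in the type I interferon list (25 measured, 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone by edgeR), whose median was −0.39. By edgeR 1 was lower without MCTO 1, and 1 rose and 1 fell with no filter on low counts. Camera called it lower (adjusted p = 0.00675; adjusted p = 0.651 with an estimated correlation), a call lost without WT 1 (0.094), MCTO 2 (0.211) or MCTO 3 (0.0614). The MAF family, relatives and partners of Mafb, had no call among 10 measured by edgeR, with 5 at an unadjusted p under 0.05, and 2 rose adjusted over the list alone. DESeq2 and limma-voom each called Maff higher (adjusted p = 0.00784 and 0.0445), and edgeR called 1 member higher with library totals alone, with no filter on low counts and with the proximal tubule covariate. The largest changes there were Maff at 1.26 ± 0.32 and Mafa at 0.92 ± 0.27 (camera adjusted p = 0.161). In the p53 list 1 rose and 1 fell of 18 adjusted over the list alone and none over all genes by the 3 tools, with 4 at an unadjusted p under 0.05 by edgeR (camera adjusted p = 0.724). By edgeR 3 members fell with no filter, which kept 20, and 1 with the tubule covariate. Of the NRF2 and antioxidant (28 measured), nuclear oxidative phosphorylation (48), cytosolic ribosomal protein (47), sex-linked (6) and sex-biased kidney (16) genes, none passed over all genes by the 3 tools or adjusted over the list alone by edgeR. An unadjusted p under 0.05 by edgeR was found for 2, 0, 2, 0 and 0 of them. Their camera adjusted p-values were 0.823, 0.87, 0.0502, 0.161 and 0.173. The ribosomal list passed as lower without WT 3 (0.0235) or MCTO 2 (0.0134), with DESeq2 size factors (0.0471), upper-quartile factors (0.0449) or the stricter filter (0.0475) and on ranks (0.027), and gave 0.594 with an estimated correlation. The sex-biased list passed as lower without WT 3 (0.00252) or MCTO 2 (0.0134), and its median went from −0.20 to 0.05 with the structural RNA covariate. The oxidative phosphorylation list passed as lower without MCTO 2 (0.0134), where 1 member was called lower by edgeR, and as higher without MCTO 3 (0.0323). The NRF2 median and mean were −0.03 and −0.02 with an upward camera direction. The oxidative phosphorylation median was 0.01 and its mean −0.01, with a downward direction by camera and an upward one by fry. The Y-linked gene Ddx3y was expressed in all 6 libraries, at 69.0 ± 4.65 CPM in WT and 73.7 ± 3.12 CPM in MCTO.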

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

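Of the tests here, the tubule covariate and upper-quartile factors for the list tests were chosen after the result was seen. All 526 called genes that were tested kept their direction under every alternative run. For the 20 genes with the largest changes, 335 of 340 alternatives gave the same call and 5 a weaker one, all for Mmp10. Over all 62 called genes named by rule, 967 of 1053 did and 86 were weaker, and none was reversed. Mafb stayed lower and short of the threshold throughout (−0.44 to −0.13).

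The count of higher genes went from 319 to 502 with no filter on low counts, 197 with the structural RNA covariate, 157 at a change of at least 2-fold and 189 at an adjusted p under 0.01. Leaving out 1 library gave 166 to 274, the lowest without WT 2. The count of lower genes went from 207 to 436 with no filter, 364 with the tubule covariate, 131 with library totals alone, 94 with the structural RNA covariate, 89 at 2-fold and 97 at an adjusted p under 0.01. Leaving out 1 library gave 115 to 175, with 115 without WT 2 and 134 without WT 3. Fewer libraries or a stricter threshold account for part of these changes by construction, and the structural RNA covariate raised the median SE of called genes from 0.15 to 0.19; for the others the cause was not tested. Cyp4b1 (0.082), Cd8a (0.266), Cyp4a12a (0.196), Cyp2j13 (0.038) and Eif2s3y (−0.024), none of them called, changed sign with the structural RNA covariate, and the cause was not tested.

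Same-numbered libraries did not consistently deviate together. The correlations were −0.028, 0.077 and 0.195. WT 1, MCTO 1 and MCTO 2 correlated best with another number, whereas WT 2, WT 3 and MCTO 3 correlated best with their own. The numbers were therefore not taken as pairs. With the replicate block, 357 genes were higher and 257 lower, 495 of them shared with the 526 called without it. The block ended the camera call of the macrophage list (adjusted p = 0.0511).

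Camera called 10 lists, 0 with an estimated correlation and 1 by fry, and 5 to 13 with 1 library left out, the fewest without WT 1. With an estimated correlation, then by fry, then over the libraries left out, the adjusted p-values were as follows. The podocyte list gave 0.607, 0.212 and 0.000168 to 0.0227, and the basement membrane list 0.594, 0.167 and 0.000558 to 0.0891. Fibrillar matrix gave 0.594, 0.215 and 9.22e-05 to 0.0891, and 0.0526 with camera on ranks. The mesangial list gave 0.57, 0.0558 and 7.69e-08 to 1.54e-05, and the endothelial list 0.384, 0.0212 and 6.1e-11 to 3.44e-08. The macrophage list gave 0.594, 0.413 and 0.00199 to 0.533, with 0.134 under no filter and 0.0573 without structural and mitochondrial RNA. Mitochondrial mRNA gave 0.594, 0.222 and 9.97e-11 to 0.000962, and interferon genes 0.651, 0.413 and 5.67e-06 to 0.211. Heat shock and immediate early genes gave 0.594, 0.164 and 8.03e-13 to 2.57e-05, and structural RNA 0.594, 0.284 and 0.0077 to 0.374. The list of nuclear oxidative phosphorylation, not called, ranged from 0.0134 to 0.923 with 1 library left out and turned upward without MCTO 3 (0.0323). The cause was not tested. With 3 libraries per group and 7446612 to 13713436 reads, changes near 1.5-fold are mostly missed, so genes not called are not shown to be unchanged.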

Other observations

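The tests on splits of the libraries and on the segment around Mafb were set before the result was seen; all other tests in this part were chosen after it. Genes named here outside the fixed rule were chosen after their values were seen.

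Secreted proteases of the Adamts family moved in both directions. Of 14 measured, Adamts8 (3.74 ± 0.30, log2 fold change ± SE), Adamts4 (2.30 ± 0.32) and Adamts9 (1.01 ± 0.17) rose, and Adamts16 (−1.32 ± 0.19), Adamts10 (−0.63 ± 0.15) and Adamts5 (−0.56 ± 0.11) fell. This was the only 1 of 424 symbol families to hold more called genes than chance by a one-sided Fisher's exact test (Benjamini-Hochberg adjusted p = 0.00195).

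Called genes lay next to each other on the chromosomes. Among 15144 neighbour pairs of tested genes that do not overlap, 28 were called in one direction, where 10000 random placements gave a median of 6 and a 95% range that ended at 12 (permutation p = 1e-04, the smallest they can give). Without predicted genes and pairs of similar symbols, the count was 24, of which 18 were among the 28 and 6 became neighbours once genes in between were dropped, where random placements gave a median of 7 and a 95% range that ended at 13 (permutation p = 1e-04). Tnfsf15, Tnc, Pappa and Astn2, in a row from 63724603 to 66404611 on chromosome 4, were higher, with log2 fold changes of 1.6 ± 0.18, 1.5 ± 0.24, 1.15 ± 0.20 and 1.1 ± 0.10. On chromosome 6, Hpgds, Qrfprl and Ndnf (2.73 ± 0.55) were higher within 65117293 to 65712326, whereas neighbouring Smarcad1 (0.18 ± 0.13) and Prdm5 (0.34 ± 0.21) were not called. Shared regulation of chromosome segments may account for such pairs. Genes of one cell type may also lie together, which was not tested.

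Endothelial and mesangial lists were lower while most called podocyte genes were higher. No camera call of these lists passed with an estimated correlation (adjusted p = 0.384 for the endothelial, 0.57 for the mesangial and 0.607 for the podocyte list). Proximal tubule content of the libraries is argued against as the whole cause, since the tubule list means overlapped (6.22 to 7.43 in WT, 6.43 to 7.46 in MCTO). All 19 called endothelial and mesangial members stayed lower with the tubule list as a covariate. All 526 called genes were kept under that covariate, so the 19 are no separate support. More podocyte RNA in the MCTO libraries would not by itself lower podocyte genes. It leaves 4 members unexplained, Tdrd5, Sema3g, Pard3b and Pla2r1, which were past the threshold in the lower direction. These 4 do not show whether it shifted the list medians. Fewer endothelial and mesangial cells relative to podocytes may contribute, but the values do not single this out. Levels are relative to library size, so this cannot be told apart from more podocyte RNA. The endothelial and mesangial medians, −0.44 and −0.4, differed by −0.04 (95% bootstrap interval over genes −0.23 to 0.20). Against medians of this size the interval is too wide to show that both lists fell equally. Lower expression per cell could give the same values. Lower expression per cell in MCTO glomeruli stays open and was not tested.

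Heat shock and immediate early genes were lower in MCTO (list median −0.66; camera adjusted p = 0.594 with an estimated correlation). One wild-type library with a high stress response is argued against as the whole cause. Over all 26 members the median log2 fold change was −0.83 without WT 1, −0.55 without WT 2 and −0.45 without WT 3. The 95% bootstrap intervals over genes were −1.23 to −0.60, −0.82 to −0.33 and −0.91 to −0.23. They treat members as independent, though the estimated correlation was 0.29, and do not measure the spread between mice. Of the 8 called members, 8, 3 and 3 stayed called in the fits without WT 1, WT 2 and WT 3, which have fewer libraries. The mean log2 CPM of the list was 6.07 in WT 2 and 5.94 in WT 3, against 5.32 in WT 1 and 5.08 to 5.09 in MCTO. A high response in both WT 2 and WT 3 is not covered, since no fit left out both. Handling of the glomeruli that differed between the groups cannot be told apart from genotype, since the labels give no time of preparation. The median log2 fold change was −0.44 over 19 immediate early members and −1.15 over 7 chaperones. A lower chaperone response in MCTO glomeruli stays open and was not tested.

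Csf1r rose while other macrophage genes did not. More macrophages with unchanged expression per cell are argued against over the macrophage genes measured, 12 of 31 listed. The 11 other than Csf1r had a median of −0.28 (95% bootstrap interval over genes −0.73 to −0.22). This interval does not measure the spread between mice, and which cells gave the reads of these genes was not tested. Mafb is also a transcription factor of macrophages. Lower levels of these genes per macrophage could therefore hide a rise in number, which was not tested. The neighbouring gene Pdgfrb did not rise with Csf1r (−0.37 ± 0.12, not called), which argues against reads from its transcript in proportion to its level. Reads from that transcript that do not follow its level were not tested. Hmgxb3, whose exons overlap those of Csf1r, was not called (log2 fold change 0.31), and reads within the shared parts were not counted. Expression of Csf1r in another glomerular cell type stays open as a candidate explanation and was not tested.

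Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 526 called genes, and the highest other gave 303. With 10 splits the share cannot fall under 0.05. The split with 303 set WT 1, WT 2 and MCTO 2 against the rest, the libraries with the highest proximal tubule means, which points to a structure of the samples; the remaining 8 splits called 0 genes by edgeR, with 243 to 1385 at an unadjusted p under 0.05.

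Called genes were not denser around Mafb than elsewhere, so the values show no excess of calls from a linked chromosome segment. The 10 Mb window held 245 tested genes against 526 calls in all. It could not have held most calls, so the test bears on their density alone. Within 10 Mb of Mafb, 2 of 245 tested genes were called, E2f1 and R3hdml, which is 0.816% against 2.83% elsewhere (two-sided Fisher's exact test, p = 0.0515). Whether linked sequence accounts for these 2 genes was not tested and stays open. R3hdml, 3.13 Mb from Mafb, had one of the 10 largest rises named by rule (log2 fold change 5.08).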
